A study of Homo sapiens with 39 samples.

How the data were processed

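RNA of 39 samples was measured on Affymetrix human genome U133 set A arrays: 10 cultures of the parental A375 melanoma line, 15 subcutaneous and 14 lung tumours of 6 derivatives grown in a xenograft model. Per the labels, RNA was extracted with a column kit and biotin-labelled cRNA was hybridised. The deposited values are intensities on the linear scale, made by the authors with RMA (background correction, normalization between arrays and summary per probe set); the RMA version is not given in the sources used here. The table holds 22283 probe sets. The lowest intensity per array was 19.29 to 20.61, the median 146.1 to 154 and the highest 23750 to 29320, and no value was 0 or negative, so log2 was taken with no offset. No raw scans were used here, so background and probe behaviour were not analysed here.

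The annotation table gave several symbols to 1043 probe sets and none to 2169. A further 6, of 68 controls of the array maker, had 1 symbol and were left out as controls. The remaining 19065 probe sets, with 1 symbol each, gave 11963 genes, 4310 of them with several probe sets. Each gene was represented by the probe set with the highest mean over all arrays. Probe sets with several symbols or none were left out of the gene tests.

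All fits used limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a second count asked for a change of at least 2-fold. Tumours, subcutaneous tumours and lung tumours were compared with the cultures in a single fit of 3 groups over 39 arrays, with no term for derivative. The series' design sets the parental line against the xenograft model, so selection of the derivatives and growth in an animal cannot be separated. Lung and subcutaneous tumours were compared over the 29 tumour arrays with derivative as a fixed term, and derivatives with a moderated F-test with site as a fixed term. The dependence of the site difference on the derivative was an F-test of the interaction. Each derivative was also compared with the cultures.

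Gene lists, 22 of pathways and 9 of other cell types, were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the 31 lists. The lists covered pigment cell lineage, invasive state, structural matrix, matrix remodelling, adhesion and integrins, metastasis promoting and suppressing genes, hypoxia, glycolysis, oxidative phosphorylation, mitosis, DNA replication, cholesterol synthesis, interferon response, MHC class I and II, NF-kB inflammation, endoplasmic reticulum and amino acid stress, MAP kinase output, p53 targets, TGF-beta targets and angiogenic factors. Those of other cells covered fibroblast, endothelial, myeloid, lymphocyte, lung epithelial, keratinocyte, adipocyte, skeletal muscle and erythroid markers. Members were also adjusted over the list alone.

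The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names the 10 largest rises and 10 largest falls against the cultures among called genes on the same side in all 12 combinations of derivative and site. It names the 8 largest rises and 8 largest falls between sites among called genes that share direction in at least 5 derivatives, and the 12 genes with the largest range between derivative means. It also names per list the 3 called members of largest change and the member of largest adjusted p, and always ADGRG1, RHOC, FN1, TMSB4X, MITF, AXL, VEGFA, COL1A2 and SFTPC. As examples of lists, members whose call held with each array left out were preferred, a choice made after values were seen.

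The results were also computed with the mean of all probe sets of a gene, every probe set on its own, brighter genes alone, median, quantile and reference gene scaling (9 of 11 stable genes measured), an offset of 32, trend and robust moderation, array weights, each derivative and each array left out, and other models for derivative and replicates. They were computed as well with camera with an estimated correlation and lists without markers of other cells. Added after the data were seen were cultures 7 and 8 averaged, 2 array covariates (the hybridisation controls and the ACTB 3' to 5' ratio), and fits without MEA2 lung tumours A and B or without the SM tumours and cultures 1 and 2. To separate the cultures shared by both sites, cultures 1, 3, 5, 7 and 8 were set against the subcutaneous and the rest against the lung tumours. This split was changed, after a first run with alternating cultures, so that the near-identical cultures 7 and 8 stayed together. The letters of replicates were not used as pairs except as an alternative, since no label says that a letter marks an animal.

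Permutation tests of single values shuffled labels between groups. The fits were tested on simulated data with 200 changed genes of 11963. Of changes of 1 on the log2 scale, 100% were recovered for tumours against cultures, 98.1% and 96.7% for the separate sites, 96.7% between sites, 95.9% between derivatives and 69.5% for the interaction. Of changes of 0.5 the shares were 85.4%, 83.3%, 81.5%, 93.6%, 78.6% and 4.8%. The false share was 4.2% to 7.8%. The simulated arrays were independent, with no differences between derivatives apart from those added, whereas real tumours of a derivative go together (correlation 0.425). These shares therefore do not measure the error of the real comparisons with cultures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.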

Results

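Expression was measured on Affymetrix human genome U133 set A arrays in A375, an established human melanoma line, and in tumours that derivatives of this line formed in a xenograft model. The labels call the parental line poorly metastatic and the tumours highly metastatic. There were 10 parental cultures, 15 subcutaneous tumours and 14 lung tumours. The tumours came from 6 derivatives, which the labels name without describing their origin. SM gave 2 subcutaneous and 2 lung tumours, MEA2 and MEA3 each gave 2 and 3, and MEC1, MEC2 and MED1 each gave 3 and 2. The median intensity per array lay between 146.1 and 154, and the lowest intensity between 19.29 and 20.61. The number of arrays limits the precision of every value. Changes below are on the log2 scale with their SE, and tumour averages are over both sites with equal weight.

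The derivatives, more than the site, set the arrays apart. MEA2 and MEA3 tumours lay at one end of the first principal component, which held 32.2% of the variance. SM tumours lay at the low end of the second component, which held 18.2%, with parental cultures 1 and 2 next to them. MEA2 lung tumours A and B scored 30.2 and 28.13 on the third component, against -4.56 for MEA2 lung tumour C. Parental cultures 7 and 8 were nearly identical, with r = 0.99939 across all probe sets. The scaled median absolute deviation of their log2 differences was 0.0601, against 0.1071 for the next closest pair of arrays. The labels give them as separate cultures, and both were counted. Averaged as 1 culture, a setting chosen after the data were seen, they gave 320 genes called between tumours and cultures instead of 445, with 101 for subcutaneous tumours and 793 for lung tumours.

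**Figure D1:**
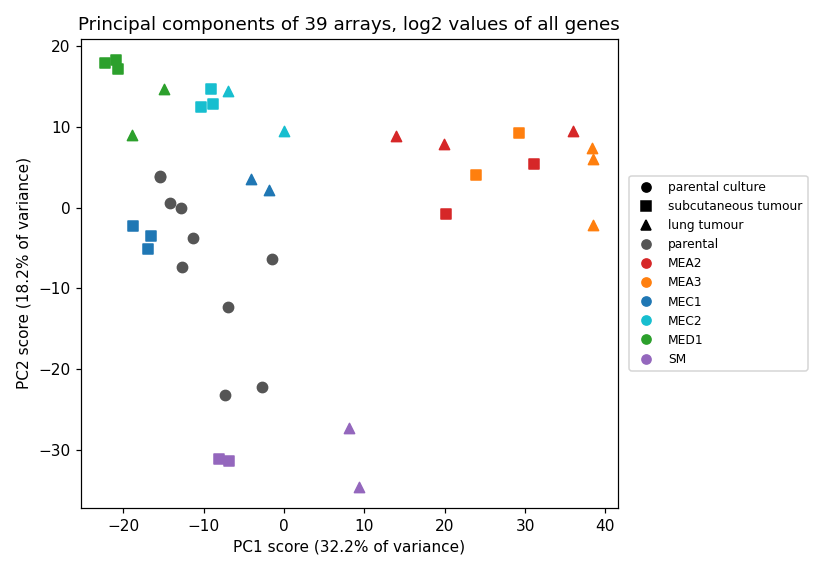
Scores of the 39 arrays on the first and second principal components of the log2 values, with colour for the derivative and marker shape for parental culture, subcutaneous tumour or lung tumour. The MEA2 and MEA3 tumours have first component scores from 13.88 to 38.49, and the SM tumours have second component scores from -34.55 to -27.27.

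Tumours of the derivatives were first compared with the parental cultures, the comparison that the series' design text names. COCH, which encodes the secreted matrix protein cochlin, was 2.88-fold higher in tumours (log2 change 1.53 ± 0.15, 29 tumours and 10 cultures, limma adjusted p = 8.9e-09). MCAM, a cell adhesion molecule of melanoma, was 1.93-fold higher (0.95 ± 0.1, adjusted p = 3.56e-08). PCLO, a scaffold protein of presynaptic terminals, was 3.88-fold lower (-1.96 ± 0.19, adjusted p = 8.9e-09). GNG4, a G protein gamma subunit, was 2.17-fold lower (-1.11 ± 0.12, adjusted p = 3.56e-08). ADGRG1, an adhesion receptor also known as GPR56, was 2.69-fold lower (-1.43 ± 0.37, adjusted p = 0.0229). This fit has no term for derivative, and with derivatives as a random block none of these genes was called.

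Of 11963 genes, 205 rose and 240 fell in tumours, and 10 of the rises and 21 of the falls were at least 2-fold. Of all 445 called genes, 63 rises and 85 falls lay on the same side of the parental mean in all 12 combinations of derivative and site. The 10 largest of those rises also included FMOD, a small leucine-rich proteoglycan that binds collagen (1.76 ± 0.38), SATB1, a chromatin organiser (1.40 ± 0.19), and FCGRT, the heavy chain of the neonatal Fc receptor (1.21 ± 0.19). PLTP, SELENBP1, PDZRN3, SERPINH1 and DRC9 completed them, with SERPINH1, a chaperone of collagen, at 0.91 ± 0.24 and DRC9 lowest at 0.80 ± 0.15. The 10 largest falls also included ITPR1, a calcium channel of the endoplasmic reticulum (-1.35 ± 0.21), PERP, a protein of desmosomes (-1.34 ± 0.29), CHRDL1, an antagonist of bone morphogenetic proteins (-1.27 ± 0.25), and DUSP10, a phosphatase of MAP kinases (-1.25 ± 0.18). ADCY1, TCN1 and SCG2 fell by 1.16, 1.13 and 1.09 on the log2 scale. Other, dimmer probe sets of ADCY1 were at -0.03 ± 0.07 and -0.02 ± 0.05. A further probe set of PCLO, of mean level 5.79, changed by 0.11 ± 0.05, while that of mean level 5.1 fell by 0.73. All 6 derivatives, each compared with the same cultures in a single fit, were called higher in 8 genes and lower in 14, among them COCH, MCAM, FCGRT, PLTP, SELENBP1, PCLO, GNG4 and DUSP10. The shared cultures make such agreement more likely.

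**Figure D2:**
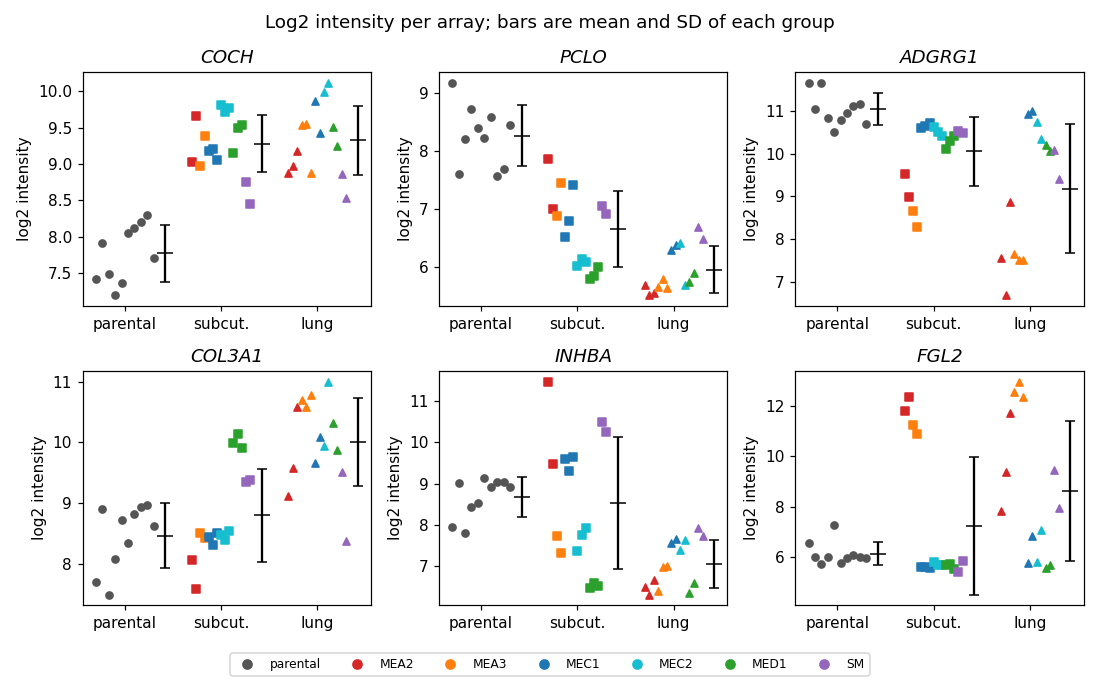
Log2 intensity of 6 genes in each array (points, coloured by derivative) with the mean and SD of the 10 parental cultures, 15 subcutaneous tumours and 14 lung tumours (bars). COCH is higher and PCLO and ADGRG1 are lower in tumours than in cultures, COL3A1 is higher and INHBA lower in lung than in subcutaneous tumours, and FGL2 has its highest values in MEA2 and MEA3 tumours, with overlap between MEA2 and SM lung tumours.

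Some genes of hypoxia and glycolysis fell in tumours. Of 23 measured hypoxia genes 5 fell, 0 rose and 18 were not called; adjusted over the list alone, 8 fell and 1 rose. As a set they shifted down (camera adjusted p = 1.85e-07), with adjusted p = 0.286 with an estimated correlation. ADM, which encodes the vasodilator adrenomedullin, changed by -1.11 ± 0.27 and the hexokinase HK2 by -0.51 ± 0.13, a call that ended with the mean of its probe sets (-0.12, adjusted p = 0.282) and with derivatives as a random block, while VEGFA was at -0.34 ± 0.15 and was not called (adjusted p = 0.222). Of 17 glycolysis genes 5 fell and 12 were not called, and 8 fell adjusted over the list alone. The set shifted down (adjusted p = 2.68e-08), with adjusted p = 0.286 with an estimated correlation. The phosphofructokinase PFKP changed by -0.73 ± 0.17. Of the 17 glycolysis genes 7 also stand in another list, and the called HK2 and PGK1 belong to the hypoxia list as well. Together the hypoxia and glycolysis lists hold 33 genes, so their shifts are not independent. With single arrays left out, the hypoxia genes that fell numbered 3 (without parental culture 7) to 5, and the glycolysis genes 2 (without parental culture 2) to 6. In MEC1 tumours 0 of 23 hypoxia genes were called lower, and the list median was -0.02.

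Inflammatory, adhesion and antigen presentation lists were also placed down with the preset correlation of camera. Of 19 genes of the NF-kB inflammatory list, TNFAIP3, an inhibitor of NF-kB signalling, fell (-0.78 ± 0.17) and 18 were not called, with 3 falls adjusted over the list alone. Camera placed the list down (adjusted p = 0.00102), with adjusted p = 0.452 with an estimated correlation. The fall was not common to all derivatives: in SM 6 of these genes were higher than in the cultures and 0 lower, with a list median of 0.10. Of 23 adhesion and integrin genes, 3 fell and MCAM rose, against 9 falls and 2 rises adjusted over the list alone. This set shifted down (adjusted p = 0.00785), with adjusted p = 0.286 with an estimated correlation. Without parental culture 2 only 1 adhesion gene was called lower. MHC class I genes (0 of 12 called, also adjusted over the list alone) shifted down (adjusted p = 0.00785), with adjusted p = 0.565 with an estimated correlation. By derivative the list median was -0.69 in MED1 and -0.42 in MEC2, against 0.18 in MEC1 and -0.15 to -0.09 in the others. MHC class II genes shifted down as well (adjusted p = 0.00923), with adjusted p = 0.452 with an estimated correlation. Of its 10 genes, 2 fell over all genes and 4 adjusted over the list alone, HLA-DQB1 among them (-0.30 ± 0.07). Its call ended with the mean of its probe sets (adjusted p = 0.0581), with scaling to reference genes (-0.19, adjusted p = 0.0626) and with derivatives as a random block. The other gene called over all genes, CD74, lost its call without any 1 of 6 cultures (limma adjusted p up to 0.0666). Of 16 TGF-beta targets 1 fell, and 4 adjusted over the list alone (camera adjusted p = 0.00785; adjusted p = 0.286 with an estimated correlation). Of 12 angiogenic factors 2 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.286 with an estimated correlation). Without parental culture 1 none of the TGF-beta targets was called, and without parental culture 3 none of the angiogenic factors. Other arrays ended these calls too: SKIL, the TGF-beta target, lost its call without any 1 of 4 arrays. The angiogenic factors ANGPTL4 and EFNA1 each lost theirs without any 1 of 9. Fry called the adhesion, TGF-beta and angiogenic lists (fry adjusted p = 0.0413 each). It did not call the NF-kB, MHC class I and MHC class II lists (fry adjusted p = 0.161, 0.236 and 0.089).

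Single members of other lists changed. KIT, a receptor of pigment cells, fell by 0.66 on the log2 scale, and was the only one of 20 pigment cell genes called; adjusted over the list alone 4 fell. MITF, the regulator of the pigment cell lineage, was at 0.10 ± 0.32 (adjusted p = 0.937). THBS1, an adhesive matrix glycoprotein, was the only one of 15 genes of the invasive state called (-0.59 ± 0.12), and AXL was at -0.08 ± 0.38 (adjusted p = 0.96). MYC rose (0.81 ± 0.21) among 18 genes of MAP kinase output, and TK1 (0.31 ± 0.07) among 24 genes of DNA replication. Of 26 structural matrix genes 5 rose and 0 fell, FMOD and the proteoglycan DCN (1.46 ± 0.28) among them, with 6 rises and 2 falls adjusted over the list alone. FN1 was at -0.96 ± 0.30 (adjusted p = 0.0628), COL1A2 at 0.36 ± 0.28 (adjusted p = 0.58), RHOC at -0.05 ± 0.07 (adjusted p = 0.839) and TMSB4X at 0.21 ± 0.2 (adjusted p = 0.67). Matrix remodelling genes went both ways, with 4 falls and 1 rise of 20 (8 and 2 adjusted over the list alone), and the lysosomal protease CTSL changed by -0.69 ± 0.15. With single arrays left out these falls numbered 2 (without parental culture 5) to 5, and the rises 0 (without parental culture 1) to 1. Of 19 genes that promote metastasis MCAM rose and CXCR4 fell (-0.93), a call that ended without any 1 of 5 arrays (adjusted p up to 0.0647), and of 12 that suppress it ADGRG1 fell. SC5D rose among 16 cholesterol synthesis genes, XBP1 rose and PPP1R15A fell among 21 genes of endoplasmic reticulum and amino acid stress, and PPM1D rose and PLK3 fell (-0.21 ± 0.04) among 15 targets of p53. The calls of SC5D, XBP1, PPP1R15A and PPM1D ended without any 1 of 7, 4, 21 and 4 arrays, at adjusted p up to 0.0849, 0.0683, 0.0919 and 0.0768. None of 25 mitosis, 27 oxidative phosphorylation and 25 interferon genes was called, also adjusted over each list alone.

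Of 12 fibroblast markers 3 rose in tumours, FAP, named here after its value was seen, fell (-0.91 ± 0.15), and 8 were not called. Beside DCN, the collagen COL3A1 rose (0.94 ± 0.25), with adjusted p of 0.0591 and 0.0661 without parental cultures 1 and 2. The set was placed up (camera adjusted p = 0.0496), with adjusted p = 0.452 with an estimated correlation, and adjusted over the list alone there were 3 rises and 1 fall. It passed in 30 of 60 settings, and not with scaling to reference genes (adjusted p = 0.708), and without parental culture 2 only 1 marker was called higher. Of these 12 genes, 9 stand in another list and 8 lay at or above the median of all genes in the parental cultures. None of 10 endothelial, 12 myeloid, 7 lymphocyte, 10 lung epithelial, 12 keratinocyte, 9 skeletal muscle and 4 erythroid markers was called; adjusted over the list alone 1 endothelial marker was. The 1 called adipocyte marker of 8 was LPL, lipoprotein lipase (0.83 ± 0.24, adjusted p = 0.0434), whose call ended without any 1 of 17 of the arrays, at up to adjusted p = 0.128. With parental cultures 7 and 8 averaged, LPL, ITGA3, PPP1R15A and LUM were among the genes no longer called.

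Of the 20 genes with the largest rises and falls, 19 kept their call with each array left out, and 17 lost it only with derivatives as a random block. With that block, in which the cultures form a single block, 1 gene was called, PRUNE2 (-0.58, adjusted p = 0.0156, named after its value was seen), and 160 had an unadjusted p under 0.05. Without parental culture 2 the count fell from 445 to 291. ADGRG1 was not called without that culture (adjusted p = 0.0524), without MEA2 or MEA3, with one value per derivative and site or without SM and cultures 1 and 2, SERPINH1 was not called without MEA3, MYC without MEA3 or MEC2, nor SCG2 without MEA3 or with one value per derivative and site.

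The cultures were next compared with tumours of each site. Subcutaneous tumours differed in 123 genes, of which 58 rose and 65 fell, and lung tumours in 1035 genes, of which 446 rose and 589 fell. SATB1 rose by 1.16 subcutaneously and 1.65 in lung, and FMOD by 1.77 and 1.75. PCLO changed by -1.61 and -2.30, DUSP10 by -1.02 and -1.48. ADGRG1 was at -0.99 in subcutaneous tumours, where it was not called (adjusted p = 0.3), and fell by 1.86 in lung tumours (adjusted p = 0.0041). PERP and SCG2 were likewise called in lung alone, at -1.94 and -1.49; within derivatives they changed between subcutaneous and lung tumours by -0.97 (adjusted p = 0.00188) and -0.55 (adjusted p = 0.0068), and ADGRG1 was not called between sites (adjusted p = 0.0789), except without MEA2 lung tumour C (-0.55, adjusted p = 0.0441). Rises shared by both sites numbered 38 and shared falls 54. The cultures stand in both comparisons, so changes go together even with no effect: the correlation across genes, which are not independent replicates, was 0.67 against 0.593 in simulations without an effect. With separate sets of 5 cultures for each site it was 0.637. The same derivatives stand at both sites in this split, and the simulations held no differences between derivatives. So neither value separates a change common to all tumours from differences between derivatives. The subcutaneous count fell to 62, 69 and 77 without parental culture 2, 1 or 3.

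Lung and subcutaneous tumours were then compared within derivatives. PDK4, a kinase that inhibits pyruvate dehydrogenase, was 2.78-fold higher in lung (1.48 ± 0.25, 14 lung and 15 subcutaneous tumours, adjusted p = 0.000561). COL3A1, a fibrillar collagen, was 2.39-fold higher (1.26 ± 0.23, adjusted p = 0.00127) and PMEL, a melanosome protein, 2.38-fold higher (1.25 ± 0.34, adjusted p = 0.0177). INHBA, a subunit of activin, was 2.89-fold lower (-1.53 ± 0.31, adjusted p = 0.00248) and MMP1, interstitial collagenase, 2.21-fold lower (-1.14 ± 0.31, adjusted p = 0.019).

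In lung tumours 598 genes rose and 873 fell, 15 and 13 of them at least 2-fold. In at least 5 of the 6 derivatives the direction was shared by 569 of the rises and 810 of the falls. The 8 largest of these rises also held the neuropeptide NTS (1.31 ± 0.30), lysozyme LYZ (1.24 ± 0.25) and the matrix protein SPARCL1 (1.15 ± 0.23). The probe sets assigned to Igk and HBE1 rose by 1.62 and 1.55, but the other probe set of HBE1, of mean level 6.87, was at -0.02 ± 0.05. The 8 largest falls also held CRYBG1 (-1.16 ± 0.14), AIM2, a sensor of cytosolic DNA (-1.13 ± 0.27), the transcription factor TFAP2B (-1.12 ± 0.23), EMP1 (-1.11 ± 0.23), PTGS2, the inducible cyclooxygenase (-1.09 ± 0.29), and ANK3 (-1.06 ± 0.13). Other probe sets of ANK3 fell less, at -0.22 ± 0.05 (mean level 7.32, against 7.33 for the one used) and -0.1 ± 0.04. MITF rose by 0.69 ± 0.18 (adjusted p = 0.0143) and TMSB4X, an actin-binding peptide, by 0.55 ± 0.15 (adjusted p = 0.0176). Fibronectin FN1 was lower, at -0.85 ± 0.19 (adjusted p = 0.00446), in 4 of the 6 derivatives. ADGRG1 was at -0.50 ± 0.19 (adjusted p = 0.0789) and was called only without MEA2 lung tumour C (-0.55, adjusted p = 0.0441), and RHOC, AXL, VEGFA, COL1A2 and SFTPC were not called, with adjusted p from 0.272 to 0.879. Other, dimmer probe sets of SFTPC were higher in lung, by 0.11 ± 0.06 to 0.32 ± 0.05.

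Oxidative phosphorylation genes shifted up in lung tumours. All 27 had positive changes, and 12 passed the test, or 15 adjusted over the list alone. The complex I subunits NDUFS4, NDUFA1 and NDUFA2 rose by 0.35, 0.34 and 0.32, but with the level of the hybridisation controls as a covariate, a setting chosen after the data were seen, they were at 0.23, 0.25 and 0.08 and were not called. NDUFA2 was also not called with array weights or without MEA3. The set shifted up (camera adjusted p = 8.94e-10), with adjusted p = 0.151 with an estimated correlation; camera still called it with that covariate. Adhesion and integrin genes shifted down: 8 of 23 fell and 0 rose, with 14 falls and 1 rise adjusted over the list alone. CD44, a hyaluronan receptor, changed by -0.72 ± 0.07, and the integrins ITGA6 and ITGB3 fell by 0.60 and 0.56. This was the one of 31 lists that held with both forms of camera (adjusted p = 1.37e-06; adjusted p = 0.041 with an estimated correlation). Without SM subcutaneous tumour A 5 adhesion genes fell.

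NF-kB inflammatory genes fell in 10 of 19, or 14 adjusted over the list alone (camera adjusted p = 1.34e-07; adjusted p = 0.316 with an estimated correlation). PTGS2 was among them, as was the cytokine LIF (-0.72 ± 0.19), which was lower in 4 of 6 derivatives. Mitosis genes fell in 7 of 25, or 12 adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.516 with an estimated correlation). PRC1, a protein of the spindle midzone, changed by -0.40 ± 0.07, and TOP2A by -0.39 ± 0.10, whereas the other probe set of TOP2A was at 0.48 ± 0.29. DNA replication genes fell in 6 of 24, or 8 adjusted over the list alone (camera adjusted p = 0.000817; adjusted p = 0.627 with an estimated correlation), with thymidylate synthase TYMS at -0.30 ± 0.08. Matrix remodelling genes fell in 3 of 20, or 8 with 1 rise adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.516 with an estimated correlation), with MMP1 and the urokinase receptor PLAUR (-0.42 ± 0.1) among them.

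Fibroblast markers rose in 6 of 12 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00207; adjusted p = 0.149 with an estimated correlation). DCN rose by 1.09 ± 0.16, POSTN by 1.09 ± 0.31 and COL3A1 as above, and the 1 fall was FAP (-0.36, adjusted p = 0.0269, named after its value was seen); without MEC1 lung tumour A 0 of the markers were called lower. LYZ was the 1 called of 12 myeloid markers, FOXJ1 (0.26 ± 0.06) the 1 of 10 lung epithelial markers, HBB (0.38 ± 0.06) the 1 of 4 erythroid markers and LIPE (0.24 ± 0.06) the 1 of 8 adipocyte markers. Of 9 skeletal muscle markers 2 fell, ACTA1 by 0.39 and TNNC2 by 0.22, and no endothelial, lymphocyte or keratinocyte marker was called. The hybridisation controls, which are added after RNA extraction, were also brighter in lung than in subcutaneous tumours, by 0.49 (10.34 ± 0.41 SD, n = 14, against 9.85 ± 0.36, n = 15, permutation p = 0.0022).

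Of the remaining lists, structural matrix genes went both ways with 5 rises and 7 falls of 26, and genes of the invasive state fell in 4 of 15, WNT5A (-0.75 ± 0.19) and the tenascin TNC (-0.72 ± 0.2) among them. Targets of p53 fell in 4 of 15, including the cell cycle inhibitor CDKN1A (-0.53 ± 0.12), and glycolysis genes in 4 of 17, including the hexokinase HK1 (-0.38 ± 0.08). PFKFB3, a regulator of glycolysis, fell with 2 others of 23 hypoxia genes (-0.57 ± 0.12). With single arrays left out, the glycolysis genes that fell numbered 2 (without MEA3 lung tumour B) to 4, and the hypoxia genes 1 (without MEC1 lung tumour A) to 3. Cholesterol synthesis, interferon response, pigment cell and MAP kinase lists had 3, 2, 2 and 4 members called, with IFIT3 at 0.27 and SPRY1, an inhibitor of growth factor signalling, at 0.57. The called cholesterol synthesis genes INSIG1, LSS and SC5D all lost their call without MEA3 lung tumour C. Without MEC2 lung tumour A 1 interferon gene was called higher. The TGF-beta targets had 5 called, angiogenic factors 2, MHC class I 2, MHC class II 1, the stress list 1, genes that promote metastasis 5 and genes that suppress it 0. Camera called none of these lists, whereas fry placed the invasive state and p53 lists down (adjusted p = 0.0208 and 0.013) and the erythroid markers up (adjusted p = 0.0208). Of the 7 lists that camera called between sites fry called 6, without DNA replication (adjusted p = 0.108). For the structural matrix, invasive state, p53, glycolysis and hypoxia lists camera gave adjusted p of 0.299, 0.0527, 0.15, 0.0562 and 0.357.

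Tested as 6 differences between derivative means, 0 genes were called by limma, with 1769 at an unadjusted p under 0.05. Over the 22 arrays whose derivative and letter occur at both sites, 854 genes were called with derivative as a term and 297 with derivative and letter as a block. Leaving out a derivative ended the site calls of PMEL (without MEC1, MED1 or SM), MMP1, LIF and PTGS2 (MEC1 or SM), MITF (MEA3, MEC1 or SM), POSTN (MEA2, MEA3 or MEC1), TNC (MEA3, MEC1 or MED1), TYMS (MEA3, MED1 or SM), IFIT3 (MEA3, MEC1, MEC2 or SM), WNT5A (MEA3 or MEC1), LIPE (MEA3 or SM), AIM2 and PLAUR (MEC1), and TMSB4X, ITGB3 and TOP2A (MEA3). With the hybridisation controls as a covariate 1051 genes were called, and FN1, TMSB4X, HBE1, POSTN, TNC, CDKN1A, HK1, LIPE, ACTA1 and TNNC2 were not. A lost call need not mean a smaller change: POSTN was at 1.11 ± 0.4 with the covariate, against 1.09 ± 0.31 without. ACTA2, which also lost its call, went from 0.22 to 0.14.

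The 6 derivatives differed from each other at the same site in 7854 genes, 65.7% of those tested, 1277 of them by at least 2-fold between the highest and lowest derivative and 222 by at least 4-fold. MEA2 and MEA3 stood apart from the other derivatives in several genes. FGL2, a fibrinogen-like protein, had a mean of 10.85 in MEA2 and 11.84 in MEA3 and between 5.64 and 7.17 in the other derivatives (adjusted p = 3.76e-08), against 6.13 in the parental cultures. Single arrays overlapped, with FGL2 at 7.83 in MEA2 lung tumour A and at 9.45 in SM lung tumour A. QPCT, glutaminyl cyclase, reached 9.20 and 10.69 in MEA2 and MEA3 against at most 5.50 elsewhere, and ANGPTL7 and RGS5 were likewise highest in MEA2 and MEA3. NPTX2, a neuronal pentraxin, was at 6.38 and 6.24 in MEA2 and MEA3 and at 9.18 to 12.12 in the others (adjusted p = 1.41e-13). The collagen gene COL6A2 and LRRC17 were likewise lowest in MEA2 and MEA3. SM had the lowest means of POSTN (6.26), TCF4 (6.99) and PLN (6.73) and the highest of CXCL8, the chemokine interleukin-8 (11.09). MMP1 was highest in MED1 (9.91) and lowest in MEA3 (5.30).

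Against the parental cultures MITF was higher by 1.07 ± 0.24 in MEA2 and 1.25 ± 0.24 in MEA3 (n = 5 each, limma adjusted p = 0.000913 and 7.83e-05) and lower in MED1, at -1.34 ± 0.24 (adjusted p = 0.000101). AXL, a receptor tyrosine kinase, changed by -1.65 in MEA3 and 1.34 in SM, and was also called lower in MEA2 (adjusted p = 4.38e-06). ADGRG1 changed by -2.67 in MEA2 and -3.07 in MEA3 and by -0.31 in MEC1, where it was not called (adjusted p = 0.632). MEA2 and MEA3 each had 16 of 23 hypoxia genes lower, with list medians of -0.51 and -0.73, and 14 and 13 of 17 glycolysis genes lower. In SM 10 of the hypoxia and 9 of the glycolysis genes were lower, with list medians of -0.37 and -0.27. Genes of DNA replication were higher in MED1 in 22 of 24 and of mitosis in 15 of 25, while 10 of 12 MHC class I genes and 9 of 20 pigment cell genes were lower there. In SM 8 DNA replication genes were lower and 2 higher, and 11 mitosis genes lower (camera adjusted p = 0.00518 and 0.000824). In MEA3 12 and 7 of them were lower and 2 and 2 higher, and camera called neither list (adjusted p = 0.132 and 0.0893). Of 25 interferon response genes 8 were higher in MEA2, 8 in MEA3 and 7 in MEC1, and 6 were lower in MED1, while 1 was lower in MEA2 and 2 in MEA3, and SM had 3 higher and 3 lower. Over the 6 derivatives 46 of 186 list tests passed with the preset correlation of camera and 0 with an estimated correlation, the lowest of these at adjusted p = 0.182.

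**Figure D3:**
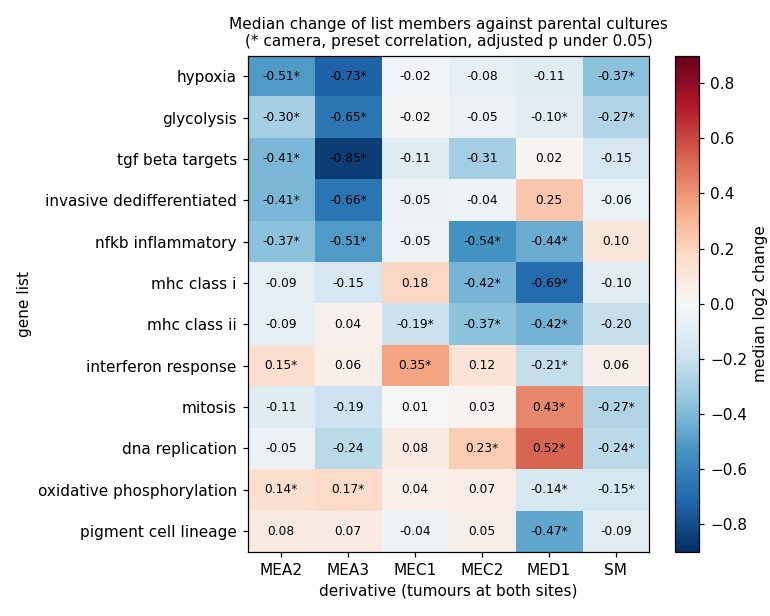
Median log2 change of the measured members of 12 gene lists (vertical axis) in tumours of each of the 6 derivatives against the 10 parental cultures (horizontal axis). Changes come from a fit with 1 site difference shared by all derivatives. Stars mark an adjusted p under 0.05 with the preset correlation of camera. Hypoxia and glycolysis medians are lowest in MEA3 (-0.73 and -0.65), and DNA replication is highest in MED1 (0.52).

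Genes called against the cultures numbered 402 in MEC1, 1551 in MEC2, 2349 in MED1, 2809 in MEA2, 3754 in MEA3 and 4198 in SM, and 1544 genes were higher in one derivative and lower in another. Between derivatives the counts ran from 14 for MEA2 and MEA3 and 210 for MEC1 and MEC2 to 5691 for MED1 and SM. The SM tumours also differed in RNA quality, with a 3' to 5' ratio of the ACTB probe sets of 0.73 ± 0.37 SD (log2, n = 4) against -0.1 ± 0.24 in the cultures (n = 10, two-sided exact permutation p = 0.003, adjusted over 2 ratios 0.003) and a GAPDH ratio of 0.54 ± 0.24 against 0.03 ± 0.1 (exact permutation p = 0.002, adjusted 0.003). SM lung tumour C, with ratios of 0.186 and 0.185, lay below parental culture 2 (0.283 and 0.273), and it scored lowest of all arrays on the second component. That culture had the highest ratios of the cultures and itself lay near the SM tumours on this component (-23.18). Without SM 5206 genes differed between derivatives.

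The difference between sites depended on the derivative in 1728 genes, 14.4% of those tested. INHBA changed from subcutaneous to lung tumours by -3.97, -2.54 and -1.90 in MEA2, SM and MEC1, and was at -0.05 in MED1 (interaction adjusted p = 7.49e-05). COL3A1 was higher in lung by 1.45 to 2.21 in MEA2, MEA3, MEC1 and MEC2, and was at 0.08 in MED1 and -0.42 in SM (adjusted p = 0.00248). Of the 1471 genes that differed between sites, 314 were among these. Tested within a single derivative, the sites differed in 1419 genes in MEA2, 1173 in SM, 1019 in MEA3, 766 in MEC1, 110 in MED1 and 22 in MEC2. The interaction count was 1100 without MEA2 subcutaneous tumour A and 3785 without MEA2 lung tumour C.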

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

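Chosen only after the results were seen were the tests of lung epithelial genes, of dilution by other cells in all tumours and in MEA2 and MEA3, and of the fibroblast list with the hybridisation controls, the control with permuted ratios for SM and the covariate and left-out array settings added later.

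Of the 59 values tested among the 10 cultures, 5 had a culture far from the other 9, measured by its gap over the range with a critical value of 0.466; chance gives about 1 in 20. SERPINH1 stood out in culture 1 (0.624), RGS5 in culture 2 (0.538), FGL2 in culture 4 (0.471), and ADCY1 and TMSB4X in culture 5 (0.475 and 0.686).

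The difference between sites depended on the derivative in 1728 genes by the interaction test. Among genes named for a site difference, the interaction adjusted p was 7.49e-05 for INHBA, 0.000102 for PDK4, 0.00112 for NTS, 0.00248 for COL3A1, 0.00266 for CRYBG1, 0.00737 for EMP1 and 0.00788 for ANK3. It was 0.0143 for AIM2, 0.0223 for TFAP2B, 0.0252 for LYZ, 0.0265 for MMP1 and 0.0408 for PMEL.

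Of 3150 probe sets without a single gene, 71 were called between tumours and cultures (2.25%, against 2.99% of probe sets with a gene) and 263 between sites (8.35% against 10.6%). The ACTB 3' to 5' ratio averaged 0.73 in SM tumours, and the hybridisation controls were 0.49 brighter in lung than in subcutaneous tumours.

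In 100 assignments of group labels, the real one included, 1 gave as many genes as the 445 of tumours against cultures, where the highest other gave 3. The same held for subcutaneous tumours against cultures (1 of 100; 123 genes, highest other 1), for lung tumours against cultures (1 of 100; 1035, highest other 0), between sites (1 of 100; 1471, highest other 18) and between derivatives (1 of 100; 7854, highest other 98), so chance is excluded at this share for the counts between sites and between derivatives, whose labels were shuffled within derivatives or sites. The 3 comparisons with cultures shuffled single arrays as if exchangeable, while tumours of a derivative go together (correlation 0.425) and the cultures form a single unit. For those counts chance is excluded only under that assumption, and with derivative as a random block 1 gene was called between tumours and cultures. For the interaction 3 of 100 gave as many as 1728, and the highest other gave 2430. As 2 other assignments gave more genes than the real one, this count can come from other structure among the tumours, and it was 1100 without MEA2 subcutaneous tumour A and 3785 without MEA2 lung tumour C.

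Of 12 fibroblast markers 6 rose in lung tumours, DCN, POSTN and COL3A1 among them, and the signal may come from host tissue, from the level of hybridisation or from the tumour cells. None of the tests of host RNA decided: the ratio of disagreement between probe sets of a gene was 0.78 (95% interval 0.58 to 1.04, permutation p = 0.11), and the fibroblast members went with LYZ, SPARCL1, HBE1 and Igk at r = 0.07 (14 lung tumours, permutation p = 0.81, and r = 0.66 without MEA2 lung tumours A and C). LYZ, SPARCL1, HBE1 and Igk were taken from the largest rises in these same tumours. Deviations were from derivative means, so in derivatives with 2 lung tumours they mirror each other, and this p treats them as independent. The lung epithelial list had a median of 0.05, with SFTPC at 8.82 and SFTPB at 8.43 in lung tumours, but a probe set that reads no host RNA would stay flat too. The other, dimmer probe sets of SFTPC, not used in this test, were higher in lung, by 0.32 ± 0.05, 0.24 ± 0.04, 0.2 ± 0.05 and 0.11 ± 0.06. The hybridisation level is argued against as the whole cause: with it as a covariate, which was called in 1164 genes, the list stayed called by camera (adjusted p = 0.0037) and the mean change was 0.99 of its size. Of the 6 members 3 stayed called (LUM and POSTN lost the call with larger errors, ACTA2 with a change of 0.14 after 0.22), so a part in single genes stays open, as does expression by the tumour cells, which was not tested; 8 of the 12 fibroblast genes lay at or above the median level in the cultures.

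Hypoxia and glycolysis lists were placed down in tumours with the preset correlation of camera, with 5 of 23 and 5 of 17 members called, ADM and PFKP among them, but adjusted p = 0.286 for both with an estimated correlation, and no hypoxia gene was called lower in MEC1. Both lists share genes, the called HK2 and PGK1 among them. Loss of signal in bright probe sets is argued against. Of 10000 random lists matched on brightness, 0 had a median as low as -0.27 for 33 genes, and their lowest was -0.14. Under the 3 other scalings the highest median was -0.16, with reference genes, where the median of all genes was 0.112. Median and quantile scaling (-0.269 and -0.278) could hardly move values that RMA had already normalized. The reference genes include GPI, which is also a glycolysis gene of the list. The values therefore argue against scaling only under this choice of reference genes. Even dilution of all transcripts is argued against for MEA2 and MEA3, where in 10 of 10 tumours the oxidative phosphorylation median lay above the hypoxia median by over 2 SD of the cultures (smallest gap 0.5, SD 0.1). These 2 derivatives were picked after their low hypoxia medians had been seen, which by itself widens the gap. Their oxidative phosphorylation medians, which even dilution would lower, lay between -0.02 and 0.35. Over all tumours the oxidative phosphorylation median lay above the hypoxia median in 22 of 29, which left the question open. It lay above in 22 of the 23 with hypoxia below the cultures, but these were picked by 1 side of the comparison, so this share decides nothing. In MEC1 hypoxia lay below the cultures in 2 of 5 tumours, both in lung, and the gap was over 2 SD in both. Their hypoxia medians were -0.174 and -0.303 and their oxidative phosphorylation medians 0.262 and 0.079, which argues against even dilution in these 2. The gap was over 2 SD in 2 of 5 MEC2 tumours, also both in lung. Their hypoxia medians were -0.186 and -0.284 and their oxidative phosphorylation medians 0.233 and 0.141, which argues against even dilution in these 2 as well. It was over 2 SD in only 0 of 5 MED1 and 2 of 4 SM tumours, so dilution stays open there and in subcutaneous MEC2 tumours. Outside MEA2 and MEA3 every tumour with such a gap was a lung tumour, and oxidative phosphorylation genes shifted up in lung, so there the gap goes with the site. RNA of cells rich in oxidative phosphorylation genes also stays open. Different oxygen supply in culture and tumour, or selection of the derivatives, may also contribute, and these were not tested.

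SM differed from the other derivatives in 5847 genes, 3244 higher and 2603 lower, and RNA quality is a candidate explanation for part of it. After taking out each gene's slope on the 3' to 5' ratios, 2165 genes (37%) stayed called in the same direction, against a median of 4429.5 and a lowest of 1976 with 50 permuted ratios, of which 1 was as low. A further 2074 genes were called only after this correction, and the slope itself was called in 97 genes, so the loss of calls does not measure how much of the difference RNA quality explains. The level of the hybridisation controls is argued against as the whole cause, since 5322 genes (91%) stayed called with it as a covariate. A difference of the derivative itself stays open beside RNA quality. SM lung tumour C had ratios of 0.186 (ACTB) and 0.185 (GAPDH), yet lay with the other SM tumours on the second component (-34.55). Its GAPDH ratio was above the highest of the 25 other tumours (0.15). Parental culture 2, with the highest ratios of the cultures (0.283 and 0.273), lay near SM at -23.18, as did culture 1 (-0.164 and 0.036) at -22.26. MEC1 lung tumour A, with 0.312 and 0.153, lay at 2.17. These single arrays go both ways.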

How the results depend on the processing

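Settings chosen after the data were seen were the 2 array covariates, cultures 7 and 8 averaged, and the fits without MEA2 lung tumours A and B or without SM and cultures 1 and 2. Signal over background limits dim genes, and counts follow the number tested: with each probe set on its own 2284 were called between sites, 13704 between derivatives and 2601 for the interaction, and with brighter genes alone 73 for subcutaneous tumours and 4608 between derivatives.

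Scaling to reference genes moved the median of all genes by 0.112, so changes are relative to it: 1860 genes were called in tumours (1723 higher, 137 lower), 941 subcutaneously and 1850 in lung. Array weights gave 1748, 586 and 2106, and 817 for the interaction; the cause was not tested for any value in this paragraph.

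With fewer arrays, counts moved both ways. Without MEA3 they were 256 (tumours), 55 (subcutaneous), 512 (lung) and 740 (between sites). Without MEC1 they were 754, 297 subcutaneous, 723 between sites and 886 for the interaction. Without MED1 they were 678, 1630 for lung and 1090 for the interaction. Without SM they were 1238, 592 and 1570, with 5206 between derivatives and 1063 for the interaction, the last 2 also without SM and cultures 1 and 2. Lung tumours alone gave 3715 between derivatives.

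Models for derivative changed tumours against cultures to 1 as a random block, 2394 with 13 cell means and 245 with one value per derivative and site. One value per derivative gave 29 subcutaneously and 662 in lung. Between sites there were 219 genes with no derivative term, 297 with derivative and letter as a block, and 0 by limma with 6 differences of derivative means (1769 at an unadjusted p under 0.05). Estimated correlation left 0 of the 9 list shifts by camera (fry called 5). The ACTB ratio as covariate gave 804 and 217 subcutaneously. The cause was not tested.

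With each array left out, tumours gave 291 (without culture 2) to 596 (without SM lung tumour C), subcutaneous tumours 62 (culture 2) to 176 (SM subcutaneous A), and the interaction 1100 (MEA2 subcutaneous A) to 3785 (MEA2 lung C).

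Of 5343 values of 88 genes against cultures, 5035 kept the side of the threshold and, for called genes, the direction, while 288 became weaker, 20 stronger and 0 reversed. A change of sign in a gene that was not called, such as AXL (-0.402 to 0.242), was not counted as reversed. Between sites 5905 of 6374 did, 2 became stronger, 1 reversed and the others became weaker: TOP2A, at 0.048 with the mean of its probe sets, which differ in sign (the other at 0.48). Between derivatives, where the F-test has no direction, 5161 of 5311 kept the side of the threshold and 150 became weaker.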

Other observations

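The test of names sharing a stem was chosen only after the result was seen. MEA2 and MEA3 tumours shared low NPTX2 (6.38 and 6.24) and low COL6A2 (8.49 and 8.73), and the interferon-induced gene MX1 was higher in both against the cultures, by 2.48 and 2.50.

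Of the 15 pairs of derivatives, MEA2 with MEA3 and MEC1 with MEC2 had the fewest genes called, 14 and 210. The exact permutation p of their summed ranks over 720 orders was 0.022, the smallest these orders can give, but these pairs had been noticed first, so the test decides nothing. The labels do not state origins.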
